A study of Mus musculus with 16 samples.

How the data were processed

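RNA was measured in 16 libraries of mouse brain that fall into 4 groups of 4: wild types kept as controls for the Prepl knockout, Prepl knockouts, wild types kept as controls for the PWS-IC deletion, and PWS-IC deleted mice. Prepl encodes prolyl endopeptidase-like, a serine hydrolase whose loss in people causes a congenital myasthenic syndrome. PWS-IC is the imprinting centre of the Prader-Willi region, which the paternally expressed genes of that region need in order to be active. Per the labels' protocols, total RNA went into Lexogen QuantSeq libraries, a kit that captures poly(A) tails and reads the ends of transcripts, so a count does not grow with the length of a transcript. The labels do not state that the replicates are separate animals, so p-values measure the spread between these samples. The 3 groups that hold both sexes come from at least 2 animals each.

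The deposited values are counts: the authors gave, for each library, a whole number of reads for each of 43472 gene symbols. The submitters' processing notes name HISAT2, HTSeq and the mm10 genome; tool versions, the gene annotation and the strand setting of the counting are not given in the sources used here. Reads of a gene and of a gene on the opposite strand therefore cannot be told apart with certainty. Each table also carries 5 totals that name no gene, which stayed out of library sizes and tests. Across the 16 libraries, 38.2% to 46.4% of the tabled reads lay in genes, 11.4% to 20.1% aligned outside genes, 0.390% to 0.479% were ambiguous, 25.2% to 31.0% did not align uniquely and 10.9% to 13.8% did not align. Reads in genes numbered 3477624 to 5852716 per library, and 19064 to 20046 genes had at least 1 read. Counts of replicates differed by more than sampling noise, with a chi-square of at least 2.52 per degree of freedom for each pair within a group, so no library was treated as a copy of another.

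Levels are given as CPM, counts scaled by the reads in genes of each library, computed here from the deposited counts, with the standard deviation over 4 libraries. Changed genes were called with edgeR 4.0.16 under R 4.3.3 on the counts as deposited. The steps were filterByExpr with its defaults (minimum count 10, minimum total count 15), TMM normalization, a quasi-likelihood fit and F-test, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Each model was fitted on its own 8 libraries with the group as the single term. The difference between the 2 models was tested as a contrast over all 16 libraries, and the wild-type groups were also set against each other. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. Gene lists with at least 5 tested members were tested with camera, with a preset correlation of 0.01 between genes, and again with a correlation estimated for each list and with fry. Library measures were compared with exact two-sided permutation tests over the 70 assignments of 8 libraries, for which the smallest possible p is 0.0286. Overlaps were tested with Fisher's exact test, two-sided. Intervals on ratios of summed reads are exact 95% Clopper-Pearson intervals and cover counting error only.

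The groups, tests, 46 gene lists, other settings and the rule for naming genes were set before the data were examined. The rule names the targeted genes in both models. It adds, among called genes with an average log2 CPM of at least 1 and no overlap between the groups, the 10 with the largest change in each direction, filled where fewer pass by up to 5 genes with the smallest p. It also takes the 4 members with the smallest p of each list that passes its test or holds a called gene, and for the contrasts the 5 smallest p in each direction. It gave 192 results for a gene in a model, after genes whose results are not reported here were left out without replacement; they stayed in all tests. Other genes named in the text were chosen after their values were seen: Ube3a and Rhoq from the lists of neighbouring genes, further members of the mitochondrial list, and the called genes on chromosome 14. The settings chosen then were RLE and upper-quartile factors, DESeq2 1.42.0, limma 3.58.1 voom with and without sample weights, other filters, a minimum fold change, sex or the replicate number as a term, 1 fit of all 16 libraries, and leaving out each library in turn. A sex term in the fit of 16 libraries, male libraries alone, thinning to the smallest library, the share of reads outside genes as a covariate, and an overlap without mitochondrial genes were added after the data had been seen.

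Sex was read from Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Coordinates are those of GENCODE M21 for GRCm38, the assembly that mm10 denotes, or of RefSeq for the same assembly where a symbol is an older synonym. Of the 13722 genes tested in the Prepl comparison 94.1% matched a single annotated gene, as did 94.6% of the 13636 tested in the PWS-IC comparison. Named pseudogenes were matched to coding transcripts with BLAST 2.17.0. The procedure was tested on simulated counts with 200 changed genes drawn from the real means and library sizes. Over 13537 simulated genes for the Prepl comparison, edgeR's test recovered 55.2% of genes changed by 0.5 on the log2 scale, 85.1% of those changed by 1 and 98.5% of those changed by 2, with 10 false calls. Over 13428 for the PWS-IC comparison the shares were 34.3%, 83.6% and 93.9%, with 7 false calls, and over 14106 for the contrast of the models they were 16.4%, 64.2% and 87.9%, with 6.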

Results

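The study asked whether loss of Prepl and loss of the Prader-Willi imprinting centre change similar genes and metabolic pathways in the brain. The 4 groups of 4 libraries were compared, each mutant with its own wild types, at 3477624 to 5852716 reads in genes per library. The wild types of the Prepl comparison were 3 females and 1 male (replicate 4), whereas the 4 Prepl knockouts were all male; each PWS-IC group held 2 males and 2 females. The share of reads that aligned outside genes was 17.0% ± 1.76 (SD, n = 4) in the Prepl wild types and 17.7% ± 1.25 in the knockouts. It was 12.3% ± 1.03 in the PWS-IC wild types and 19.1% ± 1.14 in the deleted mice, a difference of 6.80 percentage points (exact permutation test, two-sided, p = 0.0286, the smallest the design allows, Benjamini-Hochberg adjusted p = 0.0457 over 8 library measures, n = 4 per group).

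**Figure D1:**
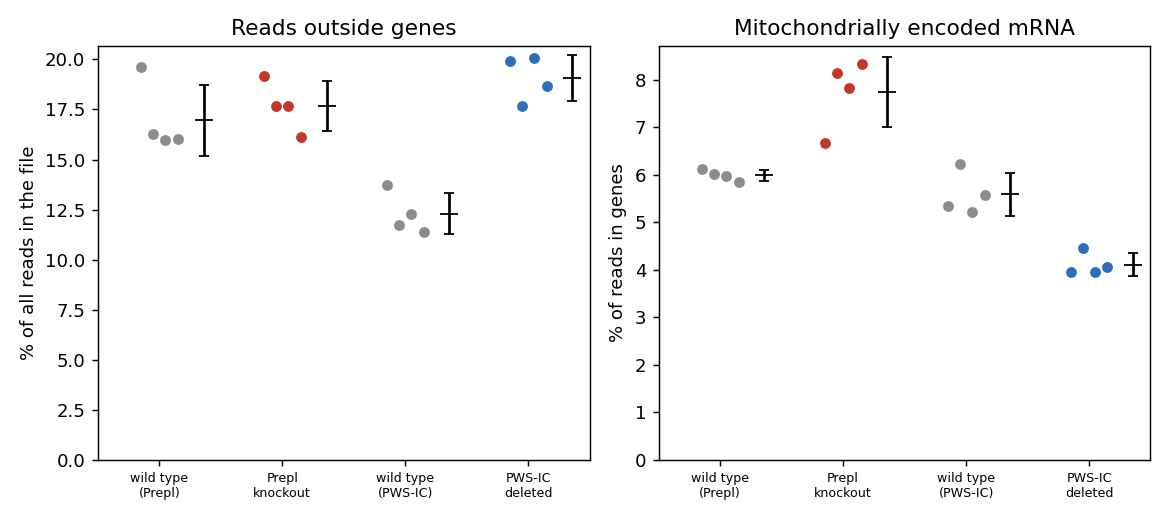
Reads that aligned outside genes (left, % of all tabled reads) and reads of the 13 mitochondrially encoded mRNAs (right, % of reads in genes). Points are the 4 libraries of each group; black marks give the mean and SD. Reads outside genes lay between 17.7% and 20.1% in the PWS-IC deleted libraries and between 11.4% and 13.7% in their wild types.

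In the Prepl knockout, Prepl itself (chromosome 17, 85063470 to 85090241) fell from 34.8 ± 1.35 CPM to 1.64 ± 0.453 CPM (SD, n = 4). That was a log2 fold change of -4.34 ± 0.191 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.44e-14). Over the 4 knockout libraries 34 reads remained against 741 in the wild types, or 4.75% of the wild-type level per read in genes (95% interval 3.26% to 6.69%). None of the 24 tested neighbours of Prepl on chromosome 17 was called in the knockout by edgeR's quasi-likelihood test, and 0 had an unadjusted p under 0.05. Outside that list but on the same chromosome, Tmem178 (80944632 to 81001816) was called, at -1.11 ± 0.150. Whether this change follows from loss of Prepl or from linkage to it was not tested. The paternally expressed Prader-Willi genes were not called there either (0 of 6 at unadjusted p under 0.05), with log2 fold changes of 0.04 ± 0.0740 for Ndn, 0.06 ± 0.0677 for Snrpn and 0.24 ± 0.127 for Magel2.

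Mitochondrially encoded mRNAs, which code for subunits of the respiratory chain and ATP synthase, rose in the Prepl knockout. Cytochrome b, mt-Cytb, went from 8071 ± 435 to 13090 ± 1470 CPM (log2 0.73 ± 0.0767), and mt-Co2, mt-Nd1 and mt-Atp6 rose by 0.50 ± 0.0741, 0.47 ± 0.0761 and 0.48 ± 0.0792. mt-Nd3 and mt-Co3 also passed, so 6 of the 13 members were higher and none lower, and 10 were higher when adjusted over the list alone. The list passed camera (Benjamini-Hochberg adjusted p = 5.12e-23; adjusted p = 0.173 with an estimated correlation). The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were not called, at 0.04 ± 0.0982 and 0.06 ± 0.0947. As a share of reads in genes, the 13 mRNAs made up 5.99% ± 0.110 in the wild types and 7.74% ± 0.742 in the knockouts (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.229 over 8 library measures, n = 4 per group).

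Among nuclear genes, Txnip, a thioredoxin-binding protein that restrains glucose uptake, rose from 54.2 ± 14.7 to 105 ± 33.3 CPM (log2 1.00 ± 0.161). Gm26782, an antisense transcript on chromosome 14, rose by 2.32 ± 0.250 on the log2 scale. Ppp1r3e, a glycogen-targeting subunit of protein phosphatase 1, rose by 2.20 ± 0.459 from a wild-type level of 0.663 ± 0.569 CPM. Cbr1, a carbonyl reductase, rose by 0.67 ± 0.136 and the metallothionein Mt2 by 0.52 ± 0.108. Of the genes that fell, Tmem178 went from 31.3 ± 5.65 to 14.2 ± 2.68 CPM and Car8, a carbonic anhydrase-related protein of Purkinje cells, changed by -1.06 ± 0.172. Rassf3 changed by -1.01 ± 0.191, the microtubule-binding Eml1 by -0.63 ± 0.129 and the glutathione-binding Lancl1 by -0.51 ± 0.106. Hba-a2, an alpha-globin gene with a near-identical neighbour, fell by 3.60 ± 0.723, from a wild-type level of 25.9 ± 27.7 CPM whose spread was as large as its mean. The acyl-CoA thioesterase Acot2 missed the threshold, at -0.98 ± 0.219. Gm28661 rose by 0.76 ± 0.125, but its 681 bases on chromosome 1 match mt-Co2 at 100% identity, so its reads cannot be separated from those of mt-Co2. Gm10116, which rose by 0.62 ± 0.128, matches the ferritin light chain gene Ftl1 at 99.6%.

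In all, edgeR's quasi-likelihood test called 36 of 13722 genes, 26 higher and 10 lower, of which 32 had no overlap between the groups. Over all genes tested 781 had no overlap, where chance gives 2.86%. Of the 24 called genes that the naming rule picked, 10 kept their call whichever library was left out: Prepl, Gm26782, Txnip, Gm28661, mt-Cytb, mt-Co2, mt-Nd1, mt-Atp6, Tmem178 and Car8. The count was 103 without wild-type replicate 1, 12 without wild-type replicate 2, 22 without wild-type replicate 3, and 23, 16 and 17 without knockout replicates 1, 2 and 4. With sex as a covariate, which leaves 1 male wild-type library to set against the 4 male knockouts, 6 genes were called, 5 of them among the 36: Prepl, Gm26782, mt-Cytb, 1500009C09Rik and Hba-a2. With a sex term in the fit of 16 libraries 36 genes were called, 18 of them among the 36 called without it.

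Besides the mitochondrial list, 7 of the 40 tested lists passed camera in the Prepl knockout. Where edgeR's quasi-likelihood test called no member, the members with an unadjusted p under 0.05 numbered 25 for the cytosolic ribosome, 6 for cholesterol synthesis, 7 for the unfolded protein response, 1 for hypothalamic neuropeptides, 1 for oligodendrocytes and 6 for other imprinted genes. The cytosolic ribosome list shifted upward, with 68 of 79 members above 0 and a median of 0.11; no member was called over all genes and 4 were when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 9.22e-11; adjusted p = 0.651 with an estimated correlation). Cholesterol synthesis shifted downward with 2 of 22 members above 0 and a median of -0.12; none was called over all genes, while 1 was higher and 2 were lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.00204; adjusted p = 0.651 with an estimated correlation). The unfolded protein response list passed toward lower values too, with the chaperones Calr at -0.37 ± 0.0961 and Canx at -0.21 ± 0.0682; of 21 members none was called over all genes and 3 were lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000671; adjusted p = 0.530 with an estimated correlation). Hypothalamic neuropeptides (0 of 20 called, also when adjusted over the list alone) passed toward lower values, with a median of -0.12 (camera, Benjamini-Hochberg adjusted p = 0.0184; adjusted p = 0.651 with an estimated correlation). Oligodendrocyte markers (0 of 8, also when adjusted over the list alone) passed toward lower values, with a median of -0.17 (camera, Benjamini-Hochberg adjusted p = 0.0445; adjusted p = 0.651 with an estimated correlation). Cerebellar markers passed as lower, with 1 of 9 called over all genes, Car8, and 3 when adjusted over the list alone; their mean was -0.26 but their median 0.01 (camera, Benjamini-Hochberg adjusted p = 0.0445; adjusted p = 0.651 with an estimated correlation). Other imprinted genes passed as higher, with none of 36 called over all genes and 4 when adjusted over the list alone, among them Nnat at 0.34 ± 0.0809, whose gene lies inside Blcap (camera, Benjamini-Hochberg adjusted p = 0.0137; adjusted p = 0.530 with an estimated correlation). None of the nuclear respiratory complex, citric acid cycle, fatty acid oxidation and glycolysis lists passed, the medians of these lists lying between -0.06 and 0.00.

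In the PWS-IC deleted brain the paternally expressed genes of the Prader-Willi region on chromosome 7 were nearly silent. Ndn (62346569 to 62350262), which encodes necdin, fell from 556 ± 11.1 to 4.30 ± 1.90 CPM (log2 -6.94 ± 0.162; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.25e-17). Snrpn (59982495 to 60140219), a splicing factor gene, fell from 344 ± 14.5 to 29.2 ± 4.95 CPM (log2 -3.54 ± 0.112), and its reads were 8.54% of the wild-type level (95% interval 7.81% to 9.34%). Magel2 fell by 5.71 ± 0.292, the long noncoding A330076H08Rik by 4.91 ± 0.371 and Mkrn3 by 4.73 ± 0.333 on the log2 scale. Peg12 had 1 read in the deleted libraries against 120 in the wild types, a ratio of 1.02% (95% interval 0.0257% to 5.81%). Snurf, which shares transcripts with Snrpn, had 0 reads in every library. D7Ertd715e, an older symbol of Snhg14 (59272737 to 60450177), fell by 3.58 ± 0.0926, and Ube3a, which it overlaps on the opposite strand, rose from 245 ± 11.01 to 380 ± 43.1 CPM (log2 0.64 ± 0.0846; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000159). Of 9 tested neighbouring genes of that region, Ube3a was the called gene. Prepl was not called, at -0.11 ± 0.133 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.727), while Rhoq, a GTPase gene near Prepl on chromosome 17, was lower, at -0.52 ± 0.120.

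**Figure D2:**
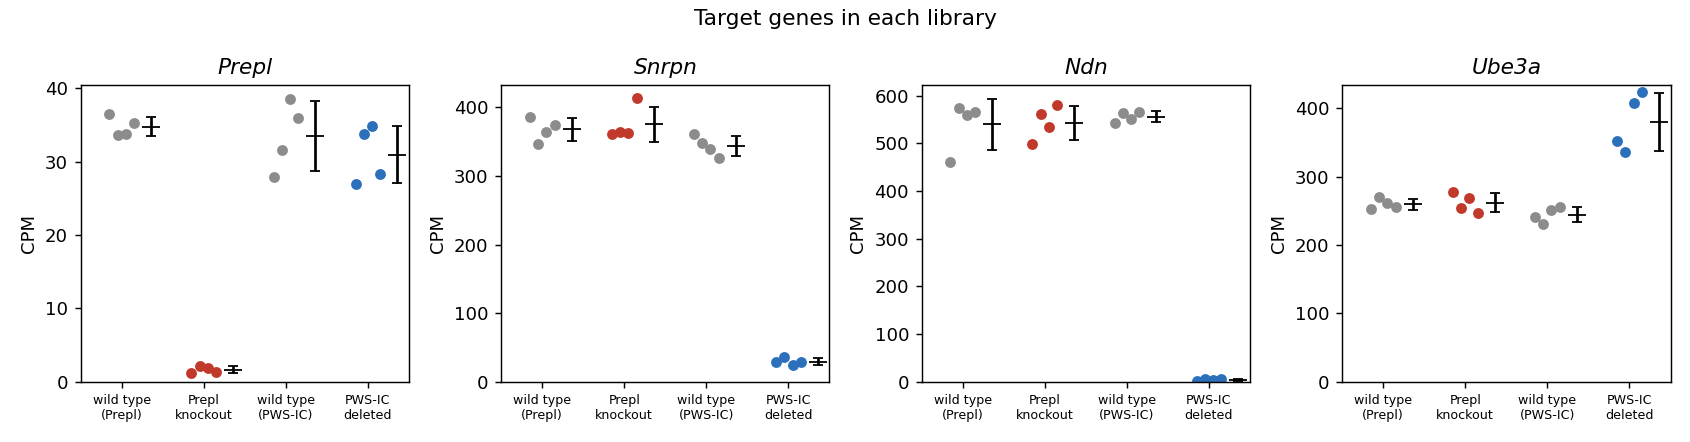
CPM of Prepl, Snrpn, Ndn and Ube3a in each library (points), with the group mean and SD (black). Prepl was at 1.64 CPM on average in its knockout; Snrpn and Ndn were at 29.2 and 4.30 CPM in the PWS-IC deleted mice, where Ube3a averaged 380 CPM.

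Mitochondrially encoded mRNAs fell in the PWS-IC deleted brain: 10 of 13 were lower and none higher over all genes, and 11 were lower and 1 higher when adjusted over the list alone. mt-Nd4l fell from 141 ± 17.9 to 51.5 ± 8.98 CPM (log2 -1.44 ± 0.123), mt-Atp8 by 0.92 ± 0.118 and mt-Nd4 by 0.67 ± 0.0792 on the log2 scale. mt-Nd4l overlaps mt-Nd4, and mt-Atp8 overlaps mt-Atp6, so reads in the shared stretch could be counted as ambiguous. The members not called over all genes were mt-Co2 at -0.12 ± 0.0721, mt-Nd3 at -0.19 ± 0.0834 and mt-Nd6 at 0.49 ± 0.167. The list passed camera (Benjamini-Hochberg adjusted p = 8.12e-15; adjusted p = 0.333 with an estimated correlation). Here the ribosomal RNAs were lower too, mt-Rnr1 by 0.40 ± 0.0767 and mt-Rnr2 by 0.29 ± 0.0717. The 13 mRNAs made up 5.59% ± 0.452 of reads in genes in the wild types and 4.10% ± 0.238 in the deleted mice (exact permutation test, two-sided, p = 0.0286, adjusted p = 0.0457 over 8 library measures, n = 4 per group), in the same libraries in which reads outside genes were more frequent. The unadjusted p was the smallest possible in both models. More of the 8 measures, some of them overlapping, reached it here, so the adjusted values do not rank the models.

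**Figure D3:**
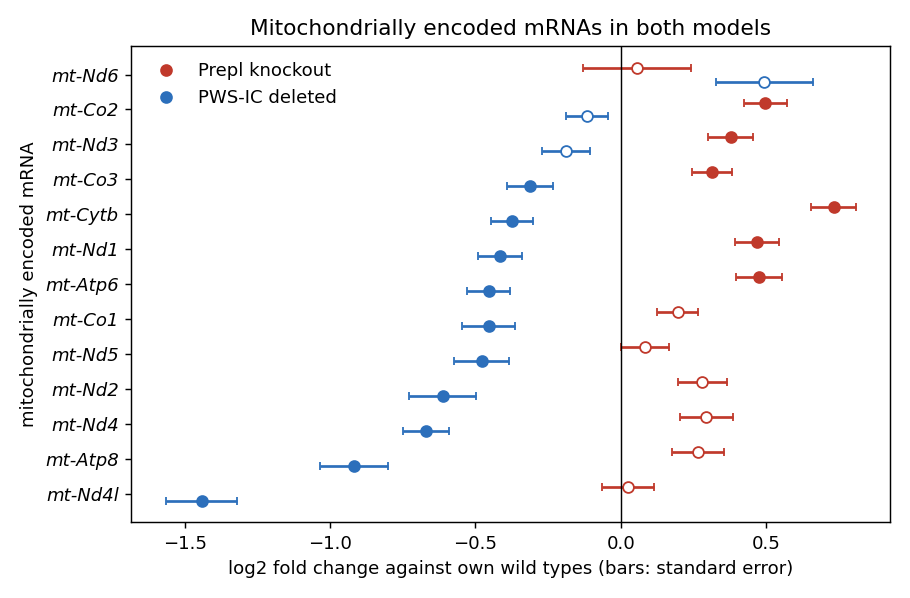
Log2 fold changes of the 13 mitochondrially encoded mRNAs in each mutant against its own wild types, with standard errors. Filled points passed an adjusted p of 0.05 and open points did not: 6 were called in the Prepl knockout, all higher, and 10 in the PWS-IC deleted mice, all lower.

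Cytosolic ribosomal protein genes moved the other way in the PWS-IC deleted brain: of 79 members 17 rose and 1 fell over all genes, and 25 rose and 2 fell when adjusted over the list alone. Rpl4 went from 696 ± 101 to 1108 ± 48.4 CPM (log2 0.68 ± 0.0918), and Rps23 and Rpl21 rose by 0.70 ± 0.120 and 0.55 ± 0.0962. The list passed camera (Benjamini-Hochberg adjusted p = 9.42e-07; adjusted p = 0.586 with an estimated correlation). With the share of reads outside genes as a covariate, which separates the groups completely and leaves few calls of any kind, none of these rises was called, and Rpl4, Rps23 and Rpl21 were at 0.63, 0.62 and 0.76. These genes have pseudogene copies that can share their reads: Gm9372, at 2.86 ± 0.437, matches Rps23 at 90.7%, and Gm15607, at 2.93 ± 0.5004, matches Rpl35 at 91.4%.

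Genes of energy metabolism changed singly in the PWS-IC deleted brain. The glycolytic enzyme genes went apart, Eno1 rising by 0.90 ± 0.157 and Pkm, which makes pyruvate kinase, changing by -0.52 ± 0.108; of 21 members 1 rose and 1 fell over all genes, and 1 rose and 2 fell when adjusted over the list alone. Pdhb, a subunit of pyruvate dehydrogenase, changed by -0.40 ± 0.0870, and the pyruvate carrier Mpc2 by 0.37 ± 0.106, the 2 called members of 25 in the citric acid cycle list (also 1 higher and 1 lower when adjusted over the list alone). Nuclear complex I had 2 of 36 members called, Ndufa5 at 0.45 ± 0.0950 and Ndufb10 at 0.43 ± 0.0943 (2 when adjusted over the list alone). Uqcrfs1 of complex III was higher at 0.36 ± 0.0913, Atp5k of complex V higher at 0.34 ± 0.0907, and Cox8a of complex IV and the mitochondrial ribosomal Mrpl34 lower at -0.36 ± 0.0998 and -0.51 ± 0.0991. The mitochondrial chaperonin Hspe1 rose by 0.65 ± 0.0921. No fatty acid oxidation gene was called by edgeR's quasi-likelihood test among 25 (3 at unadjusted p under 0.05), and none of these nuclear lists passed camera. The calls of Mpc2, Uqcrfs1, Cox8a and Atp5k were each lost when certain libraries were left out, in 5, 5, 6 and 4 of the 8 cases; those of Eno1, Pkm, Pdhb, Ndufa5, Ndufb10, Mrpl34 and Hspe1 were kept in all 8. The share of reads outside genes as a covariate separates the groups completely and leaves few calls of any kind, so it decides little. With it none of these genes was called, Cox8a and Mrpl34 turned to 0.41 and 0.18, and the other genes named in this paragraph kept their direction.

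Some markers of blood, meninges and choroid plexus were lower in the PWS-IC deleted brain than in its wild types, in libraries with more reads outside genes. Of 6 globin and other blood genes 4 fell over all genes and 5 when adjusted over the list alone, with Hba-a1 going from 711 ± 264 to 247 ± 32.5 CPM (log2 -1.52 ± 0.187) and Hbb-bs from 1487 ± 441 to 755 ± 107 CPM (log2 -0.97 ± 0.162; camera, Benjamini-Hochberg adjusted p = 3.90e-11; adjusted p = 0.161 with an estimated correlation). The PWS-IC wild types stood apart here, as their blood genes were also higher than those of the Prepl wild types. Hba-a1 was at 235.9 to 308.5 CPM in the Prepl knockouts, near the deleted level. A loss of blood genes in the deleted mice cannot be told apart from a high level in these wild types. Of 12 meningeal fibroblast genes 5 fell over all genes and 7 when adjusted over the list alone, among them the growth factor Igf2 at -0.86 ± 0.128 and the collagens Col3a1 at -0.80 ± 0.133 and Col1a2 at -0.74 ± 0.132 (camera, Benjamini-Hochberg adjusted p = 1.41e-08; adjusted p = 0.511 with an estimated correlation). Of 11 choroid plexus genes 3 fell over all genes, and 7 fell and 1 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 3.75e-05; adjusted p = 0.586 with an estimated correlation). Transthyretin, Ttr, went from 1609 ± 338 to 738 ± 585 CPM (log2 -1.12 ± 0.306), and was at -1.83 without deleted replicate 4, which stood at 1607 CPM. The calls of Ttr, Sostdc1 and Enpp2 were lost in 6, 4 and 5 of the 8 fits that left out a library. Ttr turned to 0.10 with the share of reads outside genes as a covariate, which separates these groups completely and so decides little. The other genes named in this paragraph kept their direction.

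Among called genes with an average log2 CPM of at least 1 and no overlap between the groups, the 10 that rose most in the PWS-IC deleted brain had low levels, from Gm5356 at 2.79 ± 0.499 to RP24-271K21.1 at 3.41 ± 0.443, with wild-type means between 0.444 and 1.71 CPM; 7 are annotated as noncoding RNAs or pseudogenes and 3 have no match in the annotation. Gm15839, an antisense transcript, went from 1.71 ± 0.856 to 16.4 ± 2.88 CPM, and B530045E10Rik, a long noncoding RNA, from 0.671 ± 0.496 to 5.96 ± 1.28 CPM. Outside the imprinted region the largest decreases were in Hba-a2 at -1.63 ± 0.199, AW146154 at -1.59 ± 0.427, a call lost in 6 of the 8 fits that left out a library, and Hba-a1. In all, edgeR's quasi-likelihood test called 616 of 13636 genes, 404 higher and 212 lower, of which 567 had no overlap between the groups. Over all genes tested 1603 had no overlap, where chance gives 2.86%. The count was 394 without wild-type replicate 3 and 362 without deleted replicate 1, and 1119 with sex as a covariate, 989 with the replicate number as a block and 999 in the fit of 16 libraries. With the share of reads outside genes as a covariate, which separates these groups completely, 4 genes were called, all lower.

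The mitochondrial genes called in both models changed in opposite directions, and the other shared genes in the same direction. Of 13237 genes tested in both, 34 were called in the Prepl knockout and 536 in the PWS-IC deleted mice, and 8 in both, against 1.38 for independent lists (Fisher's exact test, two-sided, p = 4.9e-05). That test ignores direction. By direction, 3 genes were higher in both against 0.616 (Fisher's exact test, Benjamini-Hochberg adjusted p = 0.038 over the direction classes). Lower in both was 1 gene against 0.143 (adjusted p = 0.168). Higher in the Prepl knockout and lower in the PWS-IC deleted mice were 4 against 0.397 (adjusted p = 0.0015), all mitochondrial. The splicing-related gene Pnisr rose in both (0.41 ± 0.0793 and 0.53 ± 0.0998), as did the noncoding Gm26782 (2.32 ± 0.250 and 0.89 ± 0.123) and RP23-109J14.2 (1.01 ± 0.201 and 1.58 ± 0.336). Hba-a2 was lower in both (-3.60 ± 0.723 and -1.63 ± 0.199). Without Prepl wild-type replicate 2 or knockout replicate 1, Gm26782 was the 1 gene called in the same direction in both models, so Pnisr was lost there. Without wild-type replicate 3 or knockout replicate 2 the genes were 2, Gm26782 with Hba-a2 or with RP23-109J14.2, again without Pnisr. In the Prepl knockout the calls of Hba-a2 and RP23-109J14.2 were lost in 6 and 4 of the 8 fits that left out a library. Hba-a1 was at -0.0256 to 0.338 in those fits. mt-Nd1, mt-Cytb, mt-Atp6 and mt-Co3 were higher in the Prepl knockout and lower in the PWS-IC deleted mice. Without mitochondrially encoded genes and the target, neighbouring and sex-linked lists, the overlap was 4 against 1.06 (Fisher's exact test, two-sided, p = 0.02, Benjamini-Hochberg adjusted p = 0.05 over the direction classes). Without those lists alone it was 8. The overlap was 4 without Prepl wild-type replicate 2, and 5 without Prepl wild-type replicate 3, knockout replicate 2 or knockout replicate 3. At an unadjusted p under 0.05 the overlap was 302 against 224 for independent lists. Of these genes 166 were higher in both against 61.1, 72 lower in both against 51.1, and 38 and 26 opposite against 54.6 and 57.1. Across genes, which are not independent replicates, the log2 fold changes of the models had a Pearson r of 0.133 and a Spearman rho of 0.148.

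Tested directly, 112 of 14392 genes changed differently between the models (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 42 toward a higher and 70 toward a lower value in the PWS-IC deleted mice. The count was 67 without Prepl wild-type replicate 2, 73 without Prepl wild-type replicate 3 and 74 without knockout replicate 3. Nelfcd, a subunit of the elongation factor NELF, differed by 0.89 ± 0.154, and the pseudogene Gm5844, which matches the chaperone gene Hsp90aa1 at 98.5%, by 0.79 ± 0.115. The mitochondrially encoded list differed by a median of -0.88, with 12 of 13 members called over all genes and 12 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.17e-37), and passed with an estimated correlation too (adjusted p = 0.00649 with an estimated correlation).

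The wild-type groups of the 2 models differed from each other in far more genes than either mutant from its own controls. The spliceosome gene Cwc22 was at 385 ± 70.8 CPM in the Prepl wild types and 11.2 ± 2.51 CPM in the PWS-IC wild types (log2 -5.07 ± 0.152), and Vcp, an ATPase gene, at 27.2 ± 2.20 and 253 ± 10.3 CPM (log2 3.26 ± 0.0917). The phosphatase gene Acp1 differed by 4.37 ± 0.207. Of 6 blood genes 5 were higher in the PWS-IC wild types over all genes and 6 when adjusted over the list alone, with a median of 1.60 (camera, Benjamini-Hochberg adjusted p = 5.1e-09; adjusted p = 0.240 with an estimated correlation). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 3275 of 13756 genes differed, 1624 higher and 1651 lower in the PWS-IC wild types. The labels name no strain, age or dissection that would separate these groups.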

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

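In this part the sex term over 16 libraries and the share of reads outside genes as a covariate were tests chosen only after the result was seen, and for the correlation the sex term was run on a second set of genes after the value of the first was known.

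Mitochondrially encoded mRNAs were higher in the Prepl knockout and lower in the PWS-IC deleted mice, and their mean difference between the models, 0.76 on the log2 scale, was reached by 1 of 100 regroupings within the models, the real grouping itself, against 0.681 for the next. The share of reads outside genes is argued against for the Prepl knockout, where the effect on the mean log2 CPM of the 13 mRNAs was 0.306 ± 0.0712 alone and 0.303 ± 0.0806 with that share as a covariate. Sex cannot be told apart from genotype there, since all knockouts were male and 3 of 4 wild types female: over 16 libraries the effect was 0.306 ± 0.0798 without and 0.221 ± 0.0869 with a sex term. In the PWS-IC deleted mice the change was -0.455 ± 0.0875, and the share of reads outside genes predicted -0.118 ± 0.171 of it, an error that leaves this explanation open. An effect of genotype on mitochondrial transcripts remains a hypothesis that may be tested by counting mitochondrial DNA copies and transcripts in littermates of a single sex.

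The log2 fold changes of the models were weakly correlated, with r = 0.133. Reads outside genes cannot be told apart: r was 0.132 given each gene's slope on that share, but these noisy slopes had an r of 0.0359 and 0.0211 with the fold changes of the models, so the correction could move little either way. Sex cannot be told apart: over the 14392 genes of the fit of 16 libraries r was 0.179 without and 0.0988 ± 0.0248 with a sex term, but over the 13237 genes tested in both models, the set run first, it was 0.133 and 0.0465, less than 0.5 of it, so the reading depends on the set of genes. Regrouped libraries gave an absolute r as large in 2 of 35 splits of the PWS-IC libraries (highest other 0.134) and in 2 of 35 splits of the Prepl libraries (highest other 0.137), so chance is not excluded. A shared response of the 2 models may be tested in new litters balanced for sex.

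Single libraries lay far from the other 3 of their group in 3 of 28 library measures tested, where 1.4 are expected by chance, and in 24 of 384 groups of gene values, where 19.2 are expected. Prepl wild-type replicate 1 had 19.6% of reads outside genes and 14.96% of its reads in its 10 highest genes, and PWS-IC deleted replicate 2 had 30.8% of reads that did not align uniquely. In the Prepl wild types, Ndn stood at 461 CPM, Mt1 at 194 CPM and Hbb-bt at 225 CPM in replicate 1 and Cbr1 at 56.2 CPM in replicate 3. In the Prepl knockouts, Snrpn stood at 413 CPM, Txnip at 155 CPM and Hba-a1 at 236 CPM in replicate 4 and Cck at 45.6 CPM in replicate 2. In the PWS-IC wild types, RP24-400M20.1 stood at 3.42 CPM and Itm2a at 46.0 CPM in replicate 1, mt-Atp6 at 6429 CPM, Timm9 at 59.4 CPM, Sostdc1 at 24.0 CPM and Tbr1 at 74.2 CPM in replicate 2, and Magel2 at 28.6 CPM in replicate 4. In the PWS-IC deleted mice, Peg12 stood at 0.241 CPM and Tef at 87.3 CPM in replicate 1, Cox7b at 384 CPM, Atp5g1 at 31.9 CPM and Cnp at 25.5 CPM in replicate 2, Cldn11 at 7.48 CPM and Wfs1 at 8.34 CPM in replicate 3, and Timm9 at 98.7 CPM and Ttr at 1607 CPM in replicate 4.

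The change of 29 named genes differed between the models, as PWS-IC minus Prepl on the log2 scale, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Among the targets the differences were -6.98 ± 0.176 for Ndn, -3.75 ± 0.121 for D7Ertd715e, -3.60 ± 0.131 for Snrpn, -5.95 ± 0.318 for Magel2, -4.59 ± 0.377 for Mkrn3, -5.01 ± 0.437 for A330076H08Rik, -6.00 ± 0.700 for Peg12 and 4.24 ± 0.239 for Prepl. Among mitochondrial mRNAs they were -1.10 ± 0.107 for mt-Cytb, -1.46 ± 0.163 for mt-Nd4l, -0.93 ± 0.114 for mt-Atp6, -0.88 ± 0.111 for mt-Nd1, -0.96 ± 0.127 for mt-Nd4, -1.18 ± 0.161 for mt-Atp8 and -0.61 ± 0.107 for mt-Co2. The insulin-like growth factor receptor Igf1r differed by -1.32 ± 0.185, Igf2 by -0.83 ± 0.161, H19 by -0.89 ± 0.179, Nnat by -0.49 ± 0.108, Col1a2 by -0.78 ± 0.174, Col3a1 by -0.84 ± 0.188 and Hba-a1 by -1.63 ± 0.266. Car8 differed by 1.33 ± 0.244, Eno1 by 1.03 ± 0.199, Tmem178 by 0.97 ± 0.213, Tef by 0.74 ± 0.156, Ap2s1 by 0.51 ± 0.107, Cbr1 by -1.02 ± 0.193 and Gm26782 by -1.42 ± 0.282. Among lists, the median difference was -0.88 for mitochondrially encoded genes, with 12 of 13 called over all genes and 12 when adjusted over the list alone. It was -0.10 for other imprinted genes (camera, Benjamini-Hochberg adjusted p = 0.0459; adjusted p = 0.428 with an estimated correlation), -0.56 for choroid plexus (adjusted p = 0.00163; adjusted p = 0.802 with an estimated correlation), -0.60 for meninges (adjusted p = 7.11e-07; adjusted p = 0.428 with an estimated correlation) and -0.64 for blood (adjusted p = 0.00982; adjusted p = 0.428 with an estimated correlation).

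Reads outside genes, on which the gene tables say nothing, averaged 19.1% in the PWS-IC deleted mice.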

How the results depend on the processing

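The sex term in the fit of 16 libraries, male libraries alone, thinning, the share of reads outside genes as a covariate and the overlap without mitochondrial genes were tests chosen only after the result was seen. The cause was not tested for any difference below. The 36 genes of the Prepl knockout were 76 with limma-voom and sample weights, 156 without a filter, 6 with sex as a covariate, 18 in the fit of 16 libraries, 36 with a sex term in that fit, 14 in male libraries alone, 61 with the share of reads outside genes as a covariate, and 12 to 103 with a library left out. The 616 genes of the PWS-IC deleted mice were 337 with a log2 change of at least 0.5, 945 without a filter, 989 with the replicate number as a block, 1119 with sex as a covariate, 999 in the fit of 16 libraries, 1233 with a sex term in that fit, 4 with the share of reads outside genes, and 362 to 653 with a library left out. The 112 genes differing between the models were 170 with DESeq2, 222 without a filter, 235 with a sex covariate and 67 to 134 with a library left out. The 3275 genes differing between wild types were 1619 with a log2 change of at least 0.5 and 2441 to 3506 with a library left out. The overlap of 8 was 5 in the fit of 16 libraries, 302 at unadjusted p under 0.05 and 4 to 12 with a library left out. It was 4 without mitochondrial genes and the target, neighbouring and sex-linked lists. The r of 0.133 was 0.0904 to 0.142 with a library left out. In the fit of 16 libraries it was 0.179 over that fit's 14392 genes and 0.133 over the 13237 genes tested in both models. The 8 lists of the Prepl knockout were 0 with an estimated correlation, 0 with fry and 4 to 10 with a library left out (5 without knockout replicate 1, 4 without knockout replicate 2); the 5 of the PWS-IC deleted mice were 0, 0 and 5 to 7. Replicate numbers were not clear pairs: only replicate 4 correlated best with its own number in each model. A block gave 35 genes in the Prepl knockout and 989 in the PWS-IC deleted mice. In the PWS-IC model r with the same number was -0.075, 0.111, 0.107 and 0.0735 for replicates 1 to 4. The mean r with the other numbers was 0.0262, -0.0434, -0.0313 and -0.0222. There replicates 1 and 2 were male and 3 and 4 female in both groups, so the block partly stands for sex.

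Of 4262 alternative values of the 192 named results, 3780 gave the same reading, called or not, 317 were weaker, 129 stronger and 36 turned direction. In the Prepl knockout these were Snrpn at -0.0509 with a sex term over 16 libraries; Ndn at -0.0293 with a sex covariate, -0.0307 in males and -0.0220 to 0.0885 with a library left out; Peg12 at -0.210 to 0.109 and A330076H08Rik at -0.00669 to 0.370 with a library left out; A330076H08Rik at -0.00129 with the share of reads outside genes. Cldn11 was at 0.0641 with a sex covariate and 0.0627 in males, Hbb-bs at -0.246 to 0.0378 with a library left out, and Hba-a1 at -0.16 with a sex term over 16 libraries and -0.0256 to 0.338 with a library left out. In the PWS-IC deleted mice all 24 turned with the share of reads outside genes: Prepl 0.43, Mirg -0.10, Cyc1 0.66, Cox8a 0.41, Cox6b1 0.10, Mrpl34 0.18, Idh3b 0.22, Cs 0.0294, Prdx1 0.0476, Ap1m1 0.00225, Furin -0.16, Nhlh2 -0.41, Tef -0.0376, Per3 -0.77, Per1 0.40, Ifitm3 0.11, Rtp4 0.61, Cnp 0.19, C1qc 0.26, Ttr 0.10, Ppp1r1b 0.19, Tac1 0.11, Prox1 0.32 and Tbr1 -0.28. That covariate separates the PWS-IC groups completely, so these turns decide little.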

Other observations

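The search of 20-megabase windows was the test in this part chosen only after the result was seen.

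Of 19 appetite and growth receptor genes 2 fell in the PWS-IC deleted brain, over all genes and when adjusted over the list alone, and the list did not pass camera (Benjamini-Hochberg adjusted p = 0.0919). Igf1r, the receptor of insulin-like growth factor 1, fell from 47.6 ± 12.1 to 22.6 ± 3.14 CPM (log2 -1.07 ± 0.168), and Irs2, which relays insulin signals, was at -0.76 ± 0.214, a call lost in each of the 8 fits that left out a library. Of 35 other imprinted genes 2 rose and 4 fell over all genes, and 4 rose and 5 fell when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.542). Among them H19 changed by -0.55 ± 0.1398, Dcn by -0.73 ± 0.146 and the paternally expressed Zrsr1 by 0.44 ± 0.0844. The meningeal list, which fell in the same libraries, had a median of -0.70. Meg3, a noncoding RNA of the maternal Dlk1-Dio3 region, rose from 2806 ± 220 to 4960 ± 926 CPM. It was the called 1 of 8 genes in a separate list of that region, where 3 rose when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.229). Vamp2, a fusion protein of synaptic vesicles, rose by 0.63 ± 0.0866, the clathrin adaptor subunit Ap2s1 by 0.46 ± 0.0813 and the granule proteins Chgb and Scg2 by 0.44 ± 0.0982 and 0.32 ± 0.0809. They were the called 1 of 33 synaptic vesicle genes, 1 of 26 adaptor and vesicle traffic genes and 2 of 18 granule genes. When adjusted over the list alone 1, 1 and 3 rose. The medians of these lists were -0.06, -0.04 and -0.03, and none passed camera (Benjamini-Hochberg adjusted p = 0.884, 0.774 and 0.618). The antigen presentation gene B2m changed by -0.47 ± 0.0926, and single markers of glia were lower: Cnp, 1 of 8 oligodendrocyte genes, at -0.56 ± 0.142, Csf1r, 1 of 12 microglial genes, at -0.63 ± 0.173 and Sox9, 1 of 12 astrocyte genes, at -0.42 ± 0.0998. When adjusted over the list alone 1, 1 and 2 were lower, and none of these lists passed camera (Benjamini-Hochberg adjusted p = 0.337, 0.212 and 0.197). The calls of H19, Chgb, Scg2, Cnp, Csf1r and Sox9 were each lost when certain libraries were left out.

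In the Prepl knockout 6 called genes, all higher, lay on chromosome 14 between 46775567 and 66921023, although Prepl, like the called Tmem178, is on chromosome 17: Cnih1 at 0.56 ± 0.101, Samd4 at 0.50 ± 0.0993, Gm26782, Acin1 at 0.41 ± 0.0828, Ppp1r3e and Pnma2 at 0.50 ± 0.111. A 20-megabase window held 5 of the 25 placed calls, which 0.37% of 10000 random draws reached, where the median draw reached 2. In the PWS-IC libraries the median male minus female difference of these genes was 0.0408 ± 0.126, against a median change of 0.534 in the knockout. That error is over the 6 genes and not over libraries, and the genes ranged from -0.569 for Pnma2 to 0.315 for Ppp1r3e. A sex difference shared by both models is argued against. One limited to the Prepl libraries is not, since sex nearly followed genotype there. With sex as a covariate, which leaves 1 male wild-type library, only Gm26782 kept its call (Cnih1 was at 0.56 and Ppp1r3e at 3.94), and the calls of Ppp1r3e and Cnih1 were lost in 6 and 3 of the 8 fits that left out a library. The 158 tested genes between the first and last of these calls had a median of 0.05, with 96 above 0. Gm26782 also rose in the PWS-IC deleted brain, by 0.89 ± 0.123, which a stretch carried by the Prepl line alone would not explain. For the other genes a stretch of chromosome 14 inherited from another strain may be the source, and genotyping strain markers there would test it.

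Regrouping the libraries asks whether counts this large arise under other groupings. Each other split mixed libraries of the real groups, so real differences widened its spread and could lower its calls. The real split also nearly followed sex for the Prepl knockout and fully followed the share of reads outside genes for the PWS-IC deletion. A count reached by the real split alone therefore cannot be credited to the genotypes. The real grouping alone reached the count of changed genes in 1 of 35 splits for the Prepl knockout (highest other 3), for the PWS-IC deletion (1 of 35, highest other 23) and between wild types (1 of 35, highest other 0). The overlap was reached in 1 of 69 (highest other 1), but the other splits had so few calls to share that this says nothing about sharing between the models. The count between models was reached in 2 of 100. The draws that kept the PWS-IC groups and mixed the Prepl groups called 157, 99, 83 and 75 genes, so the count of 112 says little about a difference from the Prepl knockout. As many lists passed in 15 of 35 splits for the Prepl knockout (highest other 14) and in 20 of 35 for the PWS-IC deletion (highest other 12), so the numbers of lists that pass could arise by chance.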
